A study of Homo sapiens with 19 samples.

How the data were processed

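Transcript levels were measured on 19 arrays, each hybridised with RNA from IMR-90 cells, an established human fetal lung fibroblast line, grown on a mesh of collagen and chondroitin sulfate. Per the labels, each array pools the cells of 4 meshes taken at 1 time. The arrays fall into 7 times by the hours given in their titles and descriptions: 3 arrays at 1 h, 2 at 2 h, 3 at 4 h, 4 at 8 h, 3 at 12 h, 2 at 24 h and 2 at 48 h. The labels do not say that arrays of 1 time came from separate cultures, so p-values measure only the spread between these arrays, which may be partly technical. Replicate numbers follow the order of the records and pair nothing. Cells before seeding or on another surface were not analysed here, so the earliest time, 1 h, served as the reference.

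The deposited values are one linear intensity per probe set and array, for 22283 probe sets including 68 control sets. The scanner software, the summary of probes into probe sets and the scaling that the authors used are not given in the sources used here. The values were above 0 and not whole numbers, and the deposited medians of the arrays lay between 135.1 and 151.1 before scaling. The number of arrays limits the precision. Each array was multiplied by a factor that set its mean, after leaving out 2% of values at each end, to 500. The factors ran from 1.37 to 1.76. Log2 of the scaled value plus a pseudocount of 32 was then used, so a fold change understates the change of low genes. Probe sets with a mean scaled value of at least 100 over all arrays were tested, which left 16120.

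Genes were named from the probe table of the array's platform. Of the probe sets, 19071 named 1 gene, 1043 named several and 2169 were not listed there. The gene table of the reference matched 99.9% of the 1-gene entries by gene ID and replaced 0 symbols. Among the tested sets, 14195 named 1 gene, covering 9509 genes, and no gene was named from a set with several. A gene is given by the probe set with the highest mean over all arrays.

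R 4.3.3 with limma 3.58.1 was used. One linear model with a mean for each of the 7 times gave a moderated F test and 6 contrasts against 1 h, with a prior variance that followed the mean signal. A separate model gave the slope on log2 of the hours. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, and those under 0.05 were called. The 6 contrasts share the 1 h arrays, so their calls are not independent of each other and no overlap between them is reported. The test was checked on simulated data of 16120 probe sets, with 100 sets changed at each fold size. The simulated noise was drawn apart for each probe set and array, with no run effect. The shares and false calls that follow therefore need not hold for the real arrays. Of sets changed 2-fold, limma recovered 43% for 2 h, 55% for 4 h, 73% for 8 h, 56% for 12 h, 41% for 24 h and 41% for 48 h, each with 6 to 10 false calls. Of sets changed 4-fold, it recovered 85%, 91%, 94%, 96%, 80% and 90%. For the slope the shares were 68% and 96%, and for the F test 47% and 93%.

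The tests, gene lists, rule for named genes and most other settings were fixed before the data were examined. The 28 lists were immediate early genes, cytokines and NF-kB targets, hypoxia and glycolysis, angiogenesis factors, fibrillar and basement membrane matrix, collagen processing enzymes, matrix proteases and inhibitors, integrins and focal adhesion, actomyosin and SRF targets, chondroitin sulfate, proteoglycan and hyaluronan synthesis, G2/M cell cycle, DNA replication and S phase, sterol synthesis, the unfolded protein and amino acid response, heat shock response, p53 targets and growth arrest, metallothioneins, oxidative stress (NRF2) genes, interferon response, TGF-beta targets, ribosomal proteins, oxidative phosphorylation, nucleolus and ribosome biogenesis, markers of fibroblasts, epithelium, endothelium and leukocytes, and housekeeping controls. Each list was tested with camera of limma, with a preset correlation of 0.01 and 1 probe set per gene, and adjusted over 196 tests. Named genes are, per contrast and for the slope, up to 6 with the largest rise and 6 with the largest fall among called genes, with a mean signal of at least 200 in the higher group and, for contrasts, no overlap between the arrays. Up to 4 members per list with the smallest F test p, and a set of genes of prior interest, such as VEGFA, IL6 and the main collagens, were named too. Which of these appear in the text was chosen for room after their values were seen.

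Titles of arrays share tags, which no label explains. Arrays sharing a tag, with its letter dropped, were treated as a run, giving 4 runs. Run 1 holds 4 arrays of 1, 2, 8 and 12 h, run 2 holds 4 of 4, 8, 12 and 48 h, run 3 holds 2 of 24 and 48 h, and run 4 holds 9 of 1 to 24 h. Deviations from the time means were compared between arrays of different times. The median correlation across probe sets was 0.41 for 46 pairs of the same run, 37 of them above 0.1. It was -0.21 for 107 pairs of different runs, 34 of them above 0.1. Subtracting the time mean sets arrays of 1 time against each other, so the negative value is partly built in. Same-run medians were 0.71, 0.15, 0.52 and 0.4 for runs 1 to 4, that of run 3 from 1 pair. At 24 h and 48 h, with 2 arrays each, the deviations of the 2 arrays mirror each other. The run 3 pair therefore has the same value as the pair of the replicate 1 arrays, from runs 4 and 2. It cannot show that run 3 is a batch. In run 4 single pairs went down to -0.36. The run was therefore treated as a batch, with values from a model with the run as a block, and within runs, printed beside the results. Whether runs differ in the handling of the arrays or in the cells seeded is not given in the sources used here, so the block may take out differences between cultures as well as technical ones. The counts of calls with and without the block had been seen before these correlations were computed, and the model without the block stayed the main one as fixed. No run holds both 1 h and 48 h arrays, so the block reaches that contrast only through the other times.

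Alternatives were the pseudocount, the filter, quantile normalization, the deposited values without scaling, no trend in the prior variance, array weights, the run as a fixed or random block, the 6 tags with letters as a block, run 4 alone, the arrays of the compared times alone, a 2-fold change besides the threshold, and each array left out in turn. For lists they were an estimated correlation, the median over a gene's probe sets and the run block. Leaving out both 48 h arrays, leaving out 48 h replicate 1 with the run block or for the lists, and the run block with an estimated correlation were added after seeing the data.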

Results

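The series followed IMR-90 lung fibroblasts over 48 h after seeding on a porous mesh of collagen and chondroitin sulfate, a scaffold material of tissue engineering, and asks how their transcript levels changed with time on it. The 19 arrays cover 1, 2, 4, 8, 12, 24 and 48 h with 3, 2, 3, 4, 3, 2 and 2 arrays. Signal is given as the scaled intensity, mean ± SD over the arrays of a time, and changes as log2 values with the standard error (SE) of the limma model. Trimmed means of the deposited values lay between 283.3 and 365.2 per array. The 3′ to 5′ signal ratio of the control probe sets ran from 0.941 to 1.6 for GAPDH and from 0.709 to 1.67 for ACTB. Both highest values were those of 48 h replicate 2, and 48 h replicate 1 had 1.09 and 1.34. The ratios were 1.51 and 1.45 on 1 h replicate 2, and 1.22 and 1.43 on 24 h replicate 2. Whether this bears on the 48 h changes was not tested. No pair of arrays of 1 time shared more than 0.0045% of its values, so none repeated another and all arrays were kept. The closest pair, 4 h replicates 2 and 3, differed with an SD of 0.19 on the log2 scale. At 1, 4 and 8 h the run 4 pair was the closest of its time, with SDs of 0.38, 0.19 and 0.26. Separate cultures cannot be told from repeated hybridisations of 1 RNA by these values.

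Run went with both of the first 2 principal components of the arrays, and time mainly with the second. The first principal component held 35% of the variance and the second 19.9%. Run accounted for an R² of 0.72 on the first and 0.66 on the second, and time for 0.31 and 0.76. The 4 arrays of run 1 had first-component scores from -42 to -31.7, whereas those of run 4 ran from -2.6 to 37.9. The 48 h replicate 1 array stood apart from all others. Its median rank correlation with them was 0.805, against 0.877 to 0.956 for the other 18 arrays. Its bioB spike-in signal was 1654 against 103 to 670, and its 18S ribosomal RNA signal was 8430, against 183 to 4010 on the other arrays of its run, run 2, and 61 to 139 in runs 1, 3 and 4.

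**Figure D1:**
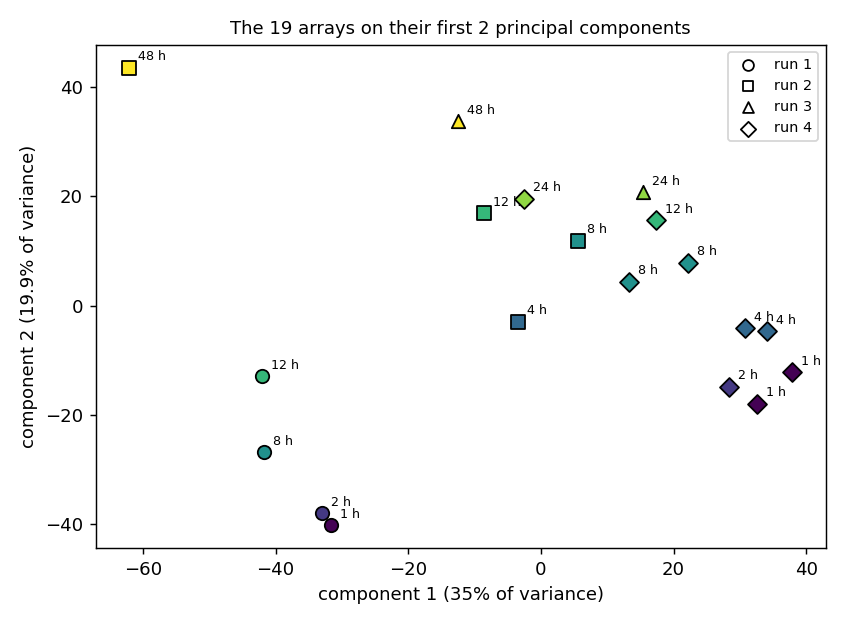
The 19 arrays on their first 2 principal components, which hold 35% and 19.9% of the variance, with time as colour and run as marker shape. The 48 h replicate 1 array lies farthest to the left, at -62.1 on the first component.

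Over all 7 times the F test of limma called 896 probe sets of 687 genes. Among them 204 had their highest mean at 1 h and 318 at 48 h, while 178 and 314 had their lowest there. By list, 19 of 30 immediate early genes, which encode transcription factors and signalling proteins induced within minutes of a stimulus, changed over the course. So did 13 of 41 genes of hypoxia and glycolysis, 7 of 27 TGF-beta targets, 6 of 33 of the unfolded protein and amino acid response and 6 of 20 of the heat shock response. Adjusted over the list alone, the counts were 25, 20, 10, 12 and 11. No member of the G2/M (51 genes), S phase (43), sterol synthesis (23) or ribosomal protein (41) lists changed by the F test without the run block, whereas 46, 23, 8 and 10 did with it. With the run as a block 4345 probe sets were called, 874 of the 896 among them, and within run 4 alone 1034. Array weights gave 4453. Without 48 h replicate 2 the count was 1415, and without both 48 h arrays 378.

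**Figure D2:**
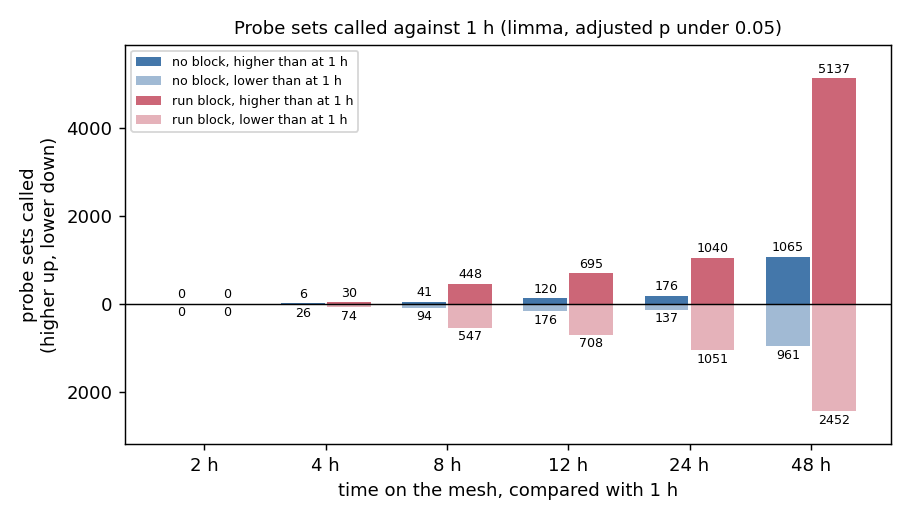
Probe sets called by limma at each time against 1 h, as bars up for higher and down for lower than at 1 h, without and with the run as a block. Bars at 48 h reach 1065 higher and 961 lower without the block, and 5137 and 2452 with it.

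At 2 h no single gene differed from 1 h past the threshold. FOS and the other immediate early genes had a median log2 change of 0.08 over 30 genes, -0.02 with the run block, 0.15 within run 1 and -0.03 within run 4, and 0 of them were called (camera adjusted p = 0.74). The camera test placed the fibrillar and basement membrane matrix list above the other genes (39 genes, median 0.16, adjusted p = 0.00017, and adjusted p = 0.31 with an estimated correlation). Its median was 0.17 with the run block, 0.21 within run 1 and 0.07 within run 4. The G2/M list lay lower, with a median of -0.61 (adjusted p = 3.5e-06, and adjusted p = 0.72 with an estimated correlation). That median was -0.15 with the run block, and within runs 1 and 4 it was -0.21 and -0.1. Camera also placed S phase genes lower (43 genes, median -0.27, -0.1 with the block, -0.07 within run 1, -0.03 within run 4, adjusted p = 0.00042, and adjusted p = 0.71 with an estimated correlation), a call that ended with the block (0.084). Respiratory chain genes (45, median -0.13, -0.11 with the block, -0.15 within run 1, -0.06 within run 4, adjusted p = 0.00013, and adjusted p = 0.68 with an estimated correlation) lay lower, as did nucleolar genes (28, median -0.1 without and with the block, -0.2 within run 1, -0.09 within run 4, adjusted p = 0.0044, and adjusted p = 0.37 with an estimated correlation). TGF-beta targets lay higher (27, median 0.12, 0.11 with the block, 0.27 within run 1, 0.04 within run 4, adjusted p = 0.0062, and adjusted p = 0.24 with an estimated correlation). Of these only 1 nucleolar gene was called over its list alone. Limma called 0 probe sets, and also 0 with the run block. Without the block 183 of 16120 had an unadjusted p under 0.05, fewer than the 5% that chance gives. The test may thus have been conservative here, and 0 calls do not show that little changed. Run 4 holds 1 array at 2 h and is not counted here.

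By 4 h several immediate early genes had fallen. FOS, a subunit of the AP-1 transcription factor, dropped from 5427 ± 4197 at 1 h to 189 ± 40.7 (SD, n = 3 and 3), an 18.6-fold fall (log2 -4.22, SE 0.56, limma adjusted p = 0.0034). The related FOSB fell 5.99-fold, from 4576 ± 282 to 785 ± 369 (adjusted p = 0.0034). The zinc finger factors KLF4 and KLF2 fell 3.54-fold and 3.31-fold, and CCN1, a secreted matrix-associated protein, 5.08-fold. CXCL2, a neutrophil-attracting chemokine, went from 3400 ± 2540 to 136 ± 60.3, an 18.1-fold fall (adjusted p = 0.012). The kinases SGK1 and SIK1 fell 4.21-fold and 5.71-fold. MAP3K4, a kinase upstream of stress-activated MAP kinases, rose from 807 ± 22.2 to 2025 ± 172 (2.45-fold, adjusted p = 0.0021), and ROR1, a receptor tyrosine kinase-like Wnt receptor, from 214 ± 10.7 to 629 ± 60.8 (2.68-fold, adjusted p = 0.0061).

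As a group, 9 of 30 immediate early genes fell at 4 h and none rose, 19 falling when adjusted over the list alone. All 30 had a log2 change below 0, with a median of -1.29, -1.13 with the run block and -1.21 within run 4 (camera adjusted p = 1.6e-41, and adjusted p = 0.016 with an estimated correlation). The cytokine list lay lower too, with 1 of 26 genes called, 3 over the list alone (median -0.2, -0.1 with the block, -0.37 within run 4, adjusted p = 0.001, and adjusted p = 0.66 with an estimated correlation). IL6 stood at 3511 ± 486 at 1 h and 1149 ± 518 at 4 h (adjusted p = 0.56, but called with array weights), and CXCL8 at 5664 ± 994 and 3347 ± 1638 (adjusted p = 1). Cell cycle lists had higher medians than at 1 h, 0.36 for G2/M (adjusted p = 0.029, and adjusted p = 0.85 with an estimated correlation) and 0.29 for S phase (adjusted p = 0.00026, and adjusted p = 0.7 with an estimated correlation). Under the run block these were -0.48 and 0.06, with camera placing G2/M lower (1.7e-15, and adjusted p = 0.3 with an estimated correlation) and not calling S phase (0.4). Within run 4 they were -0.26 and 0. Run 1 holds a 1 h array and no 4 h array. Its G2/M and S phase genes lay below those of run 4 at 1 h, by medians of -2.52 and -1.29. The medians without the block thus include these differences between runs and are not read as a rise with time. No member of these lists was called without the block, and 1 G2/M gene fell with it. Camera called 4 further lists with no called member. Hypoxia and glycolysis lay higher (41 genes, median 0.12, 0.01 with the block, 0.12 within run 4, adjusted p = 0.0019, and adjusted p = 0.66 with an estimated correlation). Sterol synthesis lay higher as well (23 genes, median 0.14, 0.1 with the block, -0.02 within run 4, adjusted p = 0.04, and adjusted p = 0.64 with an estimated correlation). Lower were TGF-beta targets (27 genes, median -0.11, -0.08 with the block, -0.14 within run 4, adjusted p = 0.012, and adjusted p = 0.27 with an estimated correlation). Also lower was the unfolded protein and amino acid response (33 genes, median -0.3, -0.08 with the block, -0.06 within run 4, adjusted p = 0.0026, and adjusted p = 0.48 with an estimated correlation). Over the list alone 3 TGF-beta targets and 1 gene of the last list fell. The first 3 of these calls ended with the run block (0.13, 0.51 and 0.084), where 2 TGF-beta targets fell, and that of TGF-beta targets also with the median over a gene's probe sets (0.1).

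Limma called 32 probe sets at 4 h, 6 higher and 26 lower. The run block gave 104, the 32 among them in the same direction, and 82 within run 4. Array weights gave 2513, 1277 higher and 1236 lower. Leaving out 1 array changed the count to 18 without 1 h replicate 2, 69 without 1 h replicate 3, with the balance turned to 51 higher and 18 lower, and 11, 10 and 4 without 4 h replicates 1, 2 and 3. FOS, FOSB, KLF4 and MAP3K4 were called with any array left out, whereas leaving out 4 h replicate 3 ended 6 of the 10 calls named here, 4 h replicate 1 ended 3, 1 h replicate 2 and 4 h replicate 2 ended 2 each, and each of 10 others ended 1, that of SIK1 or CCN1. With quantile normalization 21 probe sets were called, and SIK1 and CCN1 missed the threshold.

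**Figure D3:**
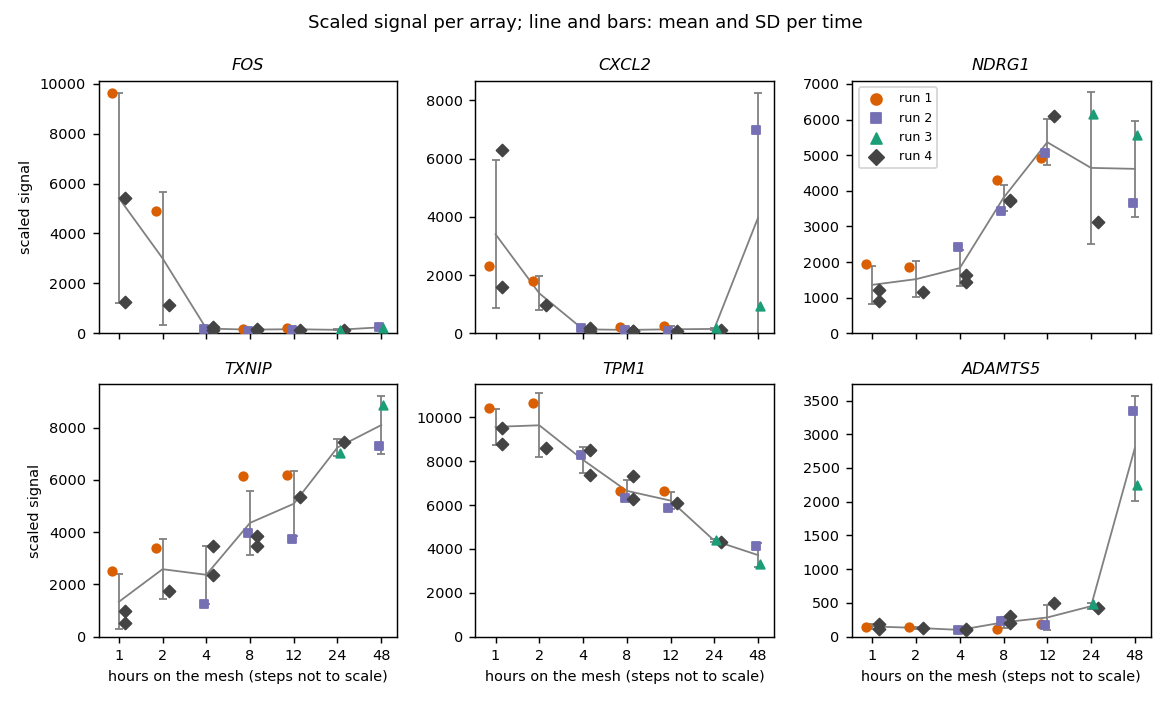
Scaled signal per array (vertical axis) against hours on the mesh for FOS, CXCL2, NDRG1, TXNIP, TPM1 and ADAMTS5, with marker by run and a line with bars for mean and SD per time. FOS falls from 5427 at 1 h to 189 at 4 h, NDRG1 rises to 5365 at 12 h, and ADAMTS5 reaches 2791 at 48 h.

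At 8 h several immediate early genes were low and other genes had risen. FOS was 23.1-fold and FOSB 14.8-fold lower than at 1 h, CXCL2 21.5-fold, and NR4A2, an orphan nuclear receptor, 7.69-fold. HMOX1, the enzyme that breaks down heme, rose from 1054 ± 160 to 5224 ± 2115 (SD, n = 3 and 4; 4.47-fold, log2 2.16, SE 0.47, limma adjusted p = 0.036). TXNIP, an inhibitor of thioredoxin, rose 3.83-fold (adjusted p = 0.037) and CSGALNACT1, which starts chondroitin sulfate chains, 3.69-fold (adjusted p = 0.022). Several genes known to respond to low oxygen rose as well: NDRG1 from 1360 ± 537 to 3805 ± 367 (2.88-fold, adjusted p = 0.014), the adenylate kinase AK4 3.53-fold, the MYC antagonist MXI1 3.52-fold, the mTOR inhibitor DDIT4 3.56-fold and the mitophagy receptor BNIP3L 2.19-fold. VEGFA, the vascular growth factor, was 3233 ± 942 at 1 h and 3022 ± 415 at 8 h (adjusted p = 0.95).

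The hypoxia and glycolysis list lay higher at 8 h, with 5 of 41 genes called, 6 over the list alone, all rising (camera adjusted p = 1.3e-07, and adjusted p = 0.4 with an estimated correlation). Its median was 0.33 without and with the block, -0.07 within run 1 and 0.46 within run 4. Of the immediate early genes 15 of 30 fell, 22 over the list alone, with a median of -1.34, -1.28 with the block, -0.66 within run 1 and -1.77 within run 4 (adjusted p = 5.4e-38, and adjusted p = 0.016 with an estimated correlation). The growth factors VEGFC, which acts on lymphatic vessels, and FGF5 fell 2.16-fold and 2.45-fold. They were the 2 called of 26 angiogenesis factors, 3 over the list alone (median -0.11, -0.08 with the block, -0.18 within run 1, -0.09 within run 4, adjusted p = 0.021, and adjusted p = 0.22 with an estimated correlation), a camera call that ended with the run block (0.07). Of 27 TGF-beta targets 3 fell and none rose, 6 and 1 over the list alone. These were CCN2 3.65-fold, ID2 2.38-fold and ID3 2.75-fold (median -0.09, -0.05 with the block, -0.06 within run 1, -0.14 within run 4, adjusted p = 0.0034, and adjusted p = 0.21 with an estimated correlation). ID2 changed by 0.03 within run 1 and by -1.86 within run 4. The atypical cyclin CCNG2 rose 3.08-fold and the protease ADAMTS1 fell 2-fold. Camera placed 3 more lists lower at 8 h. Of cytokine genes 1 of 26 fell, CXCL2, 7 over the list alone (median -0.33 without and with the block, 0.13 within run 1, -0.42 within run 4, adjusted p = 9.5e-06, and adjusted p = 0.53 with an estimated correlation). Of contractile genes 1 of 26 fell, LMOD1, 2 over the list alone (median -0.22 without and with the block, -0.25 within run 1, -0.12 within run 4, adjusted p = 0.00041, and adjusted p = 0.21 with an estimated correlation). Of the unfolded protein and amino acid response 0 of 33 were called (median -0.16, -0.1 with the block, -0.11 within run 1, -0.17 within run 4, adjusted p = 0.037, and adjusted p = 0.66 with an estimated correlation). The falling genes were 3 cytokine and 2 contractile genes without 48 h replicate 1. With the run block 5 cytokine genes, 4 angiogenesis factors, 6 TGF-beta targets, 4 contractile genes and 1 gene of the unfolded protein and amino acid response fell, and 1 contractile gene rose. CXCL3 and IL6 missed the threshold (adjusted p = 0.077 and 0.082) and passed it with the run block (0.026 and 0.016) and with array weights.

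Limma called 135 probe sets at 8 h, 41 higher and 94 lower, against 995 with the run block (448 higher and 547 lower), the 135 among them, and 731 within run 4. Array weights gave 2776 (1496 higher and 1280 lower). The balance rested on 1 h replicate 3, without which the 135 called were 83 higher and 52 lower. Without 1 h replicate 2 the count was 48, without 8 h replicate 1 it was 203, and without 8 h replicates 2, 3 and 4 it was 72, 76 and 63. Of 24 calls named or kept for this time, 7 held with any array left out, those of FOS, FOSB, CXCL2, SGK1, VEGFC, CCN2 and CCNG2. Leaving out 1 h replicate 2 ended 16 of the 24, 1 h replicate 3 ended 14, 8 h replicates 4, 2 and 3 ended 13, 12 and 10. Among others, 24 h replicates 1 and 2 ended 5 each, 4 h replicate 3 and 12 h replicate 3 ended 4 each, 4 h replicate 2 ended 3, 1 h replicate 1 and 8 h replicate 1 ended 2 each, and 4 h replicate 1 and 12 h replicate 2 ended 1 each. Quantile normalization ended the call of ID2.

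At 12 h several genes known to respond to low oxygen were higher than at 1 h. NDRG1 reached 5365 ± 645 (SD, n = 3; 4.05-fold over 1 h, log2 2.02, SE 0.3, limma adjusted p = 0.0028), and AK4, MXI1 and BNIP3L were 4.87-fold, 4.55-fold and 2.57-fold up. The neuronal enolase ENO2 rose from 448 ± 181 to 2452 ± 1178 (5.01-fold, adjusted p = 0.015), the lipid droplet protein HILPDA 5.04-fold, the transcription factor ZNF395 5.49-fold and ERO1A, an oxidase of the endoplasmic reticulum, 2.29-fold. CSGALNACT1 rose 5.33-fold, whereas XYLT1, which adds the first sugar of proteoglycan chains, fell 2.81-fold. HES1, a repressor downstream of Notch, fell from 1192 ± 302 to 189 ± 84.3 (5.68-fold, adjusted p = 0.0015), and RGS4, a regulator of G-protein signalling, 6.45-fold. VEGFA was 3310 ± 506, against 3233 ± 942 at 1 h (adjusted p = 0.9).

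Of the 41 hypoxia and glycolysis genes 9 rose at 12 h and none fell, 15 rising over the list alone (camera adjusted p = 6.7e-09, and adjusted p = 0.33 with an estimated correlation). The median was 0.46, 0.48 with the block, 0.07 within run 1 and 0.7 within run 4. Of the immediate early genes 14 of 30 fell, 25 over the list alone (median -1.62, -1.56 with the block, -0.78 within run 1, -1.87 within run 4, adjusted p = 6e-34, and adjusted p = 0.019 with an estimated correlation). Genes of the contractile cytoskeleton lay lower: 2 of 26 fell, 3 over the list alone, with the actin-binding tropomyosin TPM1 1.54-fold down (median -0.46, -0.37 with the block, -0.28 within run 1, -0.33 within run 4, adjusted p = 4.2e-07, and adjusted p = 0.09 with an estimated correlation). The nucleolus and ribosome biogenesis list also lay lower, NOP16 falling 1.91-fold as its 1 called gene of 28, with 2 over the list alone (median -0.21, -0.28 with the block, -0.1 within run 1, -0.49 within run 4, adjusted p = 4.2e-06, and adjusted p = 0.14 with an estimated correlation). In the heat shock list 2 of 20 genes fell, 4 over the list alone with 1 rising, and the HSP90 partner CHORDC1 dropped 3.07-fold (median -0.18, -0.21 with the block, -0.19 within run 1, -0.17 within run 4, adjusted p = 0.0026, and adjusted p = 0.13 with an estimated correlation). KRT18, a keratin of simple epithelia that this line also expresses, fell 2.34-fold, and CYCS, cytochrome c, 1.85-fold. Under the block 16 hypoxia and glycolysis genes rose, 6 contractile and 6 nucleolar genes fell, and 4 heat shock genes fell while 2 rose.

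Camera called 6 further lists at 12 h. TGF-beta targets lay lower, 4 of 27 falling, 5 over the list alone (median -0.27, -0.18 with the block, 0.09 within run 1, -0.26 within run 4, adjusted p = 0.0037, and adjusted p = 0.21 with an estimated correlation), with CCN2 4.73-fold and ID3 3.41-fold down. So did cytokine genes, with 1 of 26 falling, CXCL2, 3 over the list alone (median -0.18, -0.21 with the block, 0.44 within run 1, -0.64 within run 4, adjusted p = 0.00061, and adjusted p = 0.66 with an estimated correlation). S phase genes lay lower with 0 of 43 called (median -0.32, -0.24 with the block, 0.15 within run 1, -0.47 within run 4, adjusted p = 0.00042, and adjusted p = 0.71 with an estimated correlation). In the unfolded protein and amino acid response 1 of 33 fell, 1 over the list alone (median -0.18 without and with the block, -0.34 within run 1, -0.13 within run 4, adjusted p = 0.0016, and adjusted p = 0.46 with an estimated correlation). Interferon response genes lay higher, 1 of 30 rising, the immunoproteasome subunit PSMB9 2.03-fold, 1 over the list alone (median 0.22 without and with the block, 0.28 within run 1, 0.14 within run 4, adjusted p = 0.034, and adjusted p = 0.54 with an estimated correlation). Fibroblast markers lay higher with 0 of 14 called, 1 over the list alone (median 0.24, 0.15 with the block, 0.31 within run 1, 0.23 within run 4, adjusted p = 0.047, and adjusted p = 0.66 with an estimated correlation), a call that ended with the run block (0.068) and without 48 h replicate 1 (0.059). The median over a gene's probe sets ended this call and that of the interferon response (0.052 and 0.06). Without 48 h replicate 1, 3 cytokine and 3 nucleolar genes fell at 12 h. Falling under the block were 7 TGF-beta targets, 3 cytokine genes, 4 S phase genes and 8 of the unfolded protein and amino acid response, and rising were 3 interferon response genes, 2 fibroblast markers and 1 gene of the unfolded protein and amino acid response.

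At 12 h 296 probe sets were called by limma, 120 higher and 176 lower. The deposited values without scaling gave 68 and 176, and the scaling moved the median change of all probe sets from 0.034 to 0.116. With the run block there were 1403, the 296 among them, and with array weights 2949 (1666 higher and 1283 lower). Run 4 holds 1 array at 12 h and is not counted here. Without 1 h replicates 2 and 3 the counts were 86 and 141, and without 12 h replicates 2 and 3 they were 123 and 108. Of 25 calls 13 held with any array left out, among them CSGALNACT1, AK4, MXI1, NDRG1, RGS4, HES1 and CHORDC1. Leaving out 1 h replicate 2 ended 12, 12 h replicate 3 ended 10, 1 h replicate 3 and 12 h replicate 2 ended 8 each, 1 h replicate 1 ended 5 and 12 h replicate 1 ended 3, while 11 further arrays, at 2, 4, 8, 24 or 48 h, ended 1 or 2 each. KRT18 missed the threshold with quantile normalization.

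**Figure D4:**
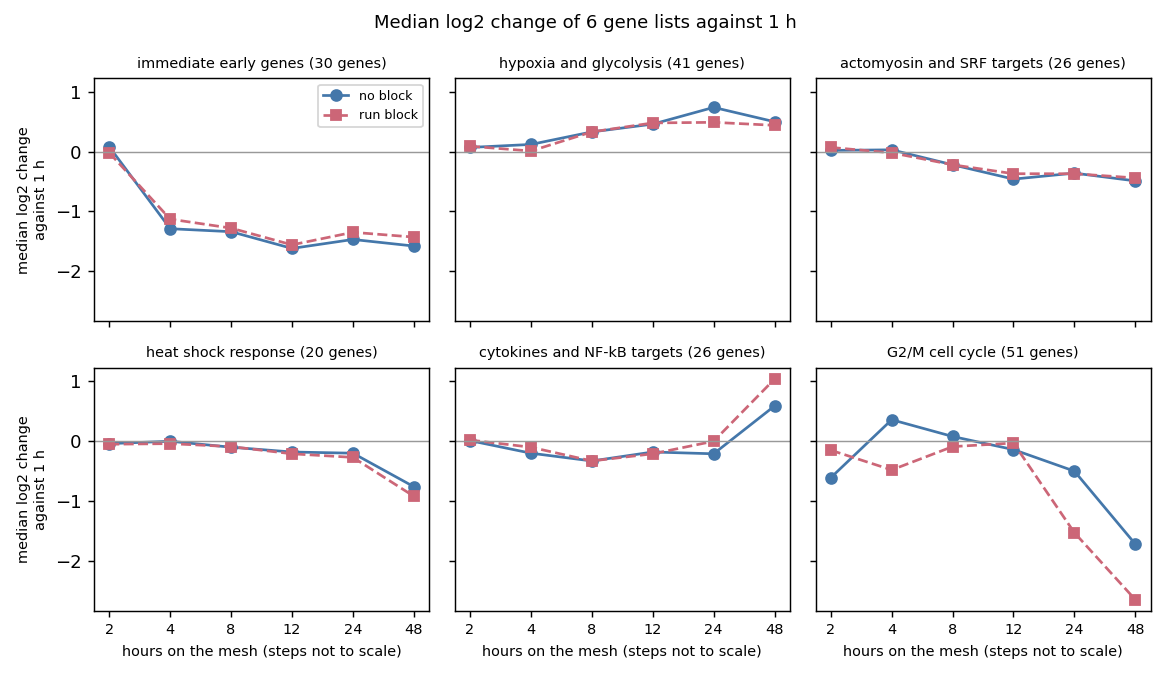
Median log2 change against 1 h (vertical axis) at each later time for 6 gene lists, with a solid line without and a dashed line with the run as a block. The immediate early list lies at -1.29 by 4 h, the hypoxia and glycolysis list reaches 0.74 at 24 h, and the G2/M list at 48 h lies at -1.72 without the block and -2.65 with it.

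At 24 h several glycolytic enzymes were higher, and IL6 and TPM1 lower, than at 1 h. The aldolase ALDOC rose from 311 ± 51.5 to 2098 ± 472 (SD, n = 3 and 2; 6.18-fold, log2 2.63, SE 0.44, limma adjusted p = 0.0061), ALDOA rose 1.64-fold, phosphoglycerate kinase PGK1 1.8-fold and FAM162A, a mitochondrial protein induced by low oxygen, 5.38-fold. The prolyl hydroxylases P4HA1 and P4HA2, which modify collagen chains, rose 2.35-fold and 2.05-fold. ITGA2, a chain of a collagen-binding integrin, rose from 1735 ± 756 to 4963 ± 181 (3.01-fold, adjusted p = 0.0096), and RGS17 4.97-fold (adjusted p = 0.00037). IL6, a cytokine, fell from 3511 ± 486 to 401 ± 95.7 (8.24-fold, adjusted p = 0.033), and TPM1 fell 2.17-fold (adjusted p = 0.0014).

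Of 41 hypoxia and glycolysis genes 13 rose at 24 h, 22 over the list alone, and under the block 18 rose and 1 fell (median 0.74, 0.49 with the block, 0.6 within run 4, camera adjusted p = 2.6e-14, and adjusted p = 0.21 with an estimated correlation). Of the immediate early genes 12 of 30 fell, 18 over the list alone (median -1.47, -1.35 with the block, -1.58 within run 4, adjusted p = 6.7e-26, and adjusted p = 0.038 with an estimated correlation). The G2/M list, genes of mitosis, had a median of -0.5 with 0 of 51 genes called, also 0 over the list alone (adjusted p = 0.0056, and adjusted p = 0.83 with an estimated correlation). Under the run block the median was -1.53 and 43 of the 51 fell, and within run 4 it was -1.61. S phase genes went the same way, with 0 of 43 called without the block and 21 with it (median -0.48, -0.74 with the block, -1.03 within run 4, adjusted p = 5.4e-07, and adjusted p = 0.66 with an estimated correlation). MKI67, the Ki-67 proliferation antigen, had a log2 change of -0.67 (SE 0.74, adjusted p = 0.89), -1.27 with the block (adjusted p = 0.00097) and -1.3 within run 4.

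Among fibroblast markers 2 of 14 rose at 24 h, 4 over the list alone: PDGFRA, a PDGF receptor, 2.3-fold and the lung mesenchyme factor FOXF1 1.78-fold (median 0.25, 0.24 with the block, 0.24 within run 4, adjusted p = 0.0021, and adjusted p = 0.4 with an estimated correlation). The collagen processing list held P4HA1 and P4HA2 as its 2 rising genes of 19, 3 over the list alone (median 0.18, 0.11 with the block, 0.25 within run 4, adjusted p = 0.034, and adjusted p = 0.66 with an estimated correlation). Both camera calls ended with the run block (0.093 and 0.76), and without 48 h replicate 1 only 1 fibroblast marker rose, with the block 5. Of 22 oxidative stress genes 1 rose, 4 over the list alone and 6 with the block, the transketolase TKT 1.62-fold (median 0.37, 0.34 with the block, 0.51 within run 4, adjusted p = 0.00057, and adjusted p = 0.22 with an estimated correlation). The oxidative phosphorylation list, subunits of the respiratory chain, had a median of 0.21 (adjusted p = 0.0082, and adjusted p = 0.77 with an estimated correlation) but -0.05 with the block (adjusted p = 0.22), and 0.11 within run 4. Its member CYCS fell 2.36-fold, the 1 called of 45, with 1 rising and 1 falling over the list alone.

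Camera placed the contractile, nucleolar and sterol lists lower at 24 h. Of 26 contractile genes TPM1 alone fell, 4 over the list alone (median -0.36, -0.37 with the block, -0.33 within run 4, camera adjusted p = 1.8e-05, and adjusted p = 0.14 with an estimated correlation). Of 28 nucleolar genes NOP16 alone fell, 4 over the list alone (median -0.35, -0.38 with the block, -0.32 within run 4, adjusted p = 6.2e-06, and adjusted p = 0.14 with an estimated correlation). Of 23 sterol synthesis genes 0 were called (median -0.33, -0.42 with the block, -0.41 within run 4, adjusted p = 0.00041, and adjusted p = 0.29 with an estimated correlation). Of 27 TGF-beta targets 1 fell, 4 over the list alone with 1 rising (median -0.24, -0.25 with the block, -0.34 within run 4, adjusted p = 0.0068, and adjusted p = 0.24 with an estimated correlation). In the heat shock list CHORDC1 fell and 1 gene of 20 rose, 2 and 1 over the list alone (median -0.2, -0.27 with the block, -0.2 within run 4, adjusted p = 0.034, and adjusted p = 0.24 with an estimated correlation), and 2 fell without 48 h replicate 1. Cytokine genes lay lower, with IL6 and CXCL2 as the 2 falling of 26, 2 over the list alone (median -0.21, 0 with the block, -0.32 within run 4, adjusted p = 0.0022, and adjusted p = 0.68 with an estimated correlation), a call that ended with the run block (0.45). Higher were interferon response genes, with PSMB9 and the transcription factor IRF7 rising of 30, 2 over the list alone (median 0.2, 0.27 with the block, 0.31 within run 4, adjusted p = 0.0029, and adjusted p = 0.37 with an estimated correlation). Ribosomal proteins lay higher too, 0 of 41 called (median 0.11, 0.18 with the block, 0.21 within run 4, adjusted p = 0.0019, and adjusted p = 0.66 with an estimated correlation). Under the block 8 contractile, 5 nucleolar, 4 sterol synthesis and 4 heat shock genes and 5 TGF-beta targets fell. Rising there were 7 ribosomal proteins, 4 interferon response genes, 2 heat shock genes, 1 sterol synthesis gene and 1 TGF-beta target.

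Limma called 313 probe sets at 24 h, 176 higher and 137 lower. The block raised this to 2091, 309 of the 313 among them. Array weights gave 2499, and run 4, with 1 array at 24 h, is not counted here. The count fell to 36 (28 higher and 8 lower) without 24 h replicate 1, 27 without 24 h replicate 2 and 109 without 1 h replicate 2. Of 32 calls only those of RGS17, FOS, FOSB, HES1 and TPM1 held with any array left out. Leaving out 24 h replicate 2 ended 26 and 24 h replicate 1 ended 23, 1 h replicates 2 and 3 ended 14 and 10, 4 h replicate 3 ended 9, and 14 further arrays ended 1 to 8 each. With a pseudocount of 8 the call of PDGFRA ended.

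At 48 h genes of the matrix and of growth factors had changed in both directions. ADAMTS5, a protease that cleaves the proteoglycan aggrecan, rose from 151 ± 35.6 to 2791 ± 774 (SD, n = 3 and 2; 15.3-fold, log2 3.94, SE 0.38, limma adjusted p = 2.1e-05). POSTN, the matrix protein periostin, rose 3.15-fold to 13307 ± 2654, the laminin chain LAMA4 4.26-fold, COL18A1 2.96-fold, the growth factors FGF7 and NRG1 3.61-fold and 4.51-fold, and PDGFRA 4.16-fold. The growth factors VEGFC and FGF5 fell 2.26-fold and 2.98-fold, calls that ended without 48 h replicate 1. Of 26 angiogenesis factors 4 rose and 5 fell, 7 and 6 over the list alone (camera adjusted p = 0.91), and without that array 3 rose and 1 fell, with the block 9 and 7. DDAH1, which degrades methylated arginines, fell from 6092 ± 469 to 736 ± 312 (8.3-fold, adjusted p = 2e-05), and the serine synthesis enzyme PSAT1 7.33-fold. HAS2, the main hyaluronan synthase, fell from 1336 ± 158 to 334 ± 17.4 (3.72-fold, adjusted p = 0.00011).

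Of the matrix list 11 of 39 genes rose at 48 h and 1 fell, 16 and 2 over the list alone (median 0.63, 0.41 with the block, camera adjusted p = 0.0036, and adjusted p = 0.48 with an estimated correlation), a call that ended with the run block (0.09). Leaving out 48 h replicate 1, 5 rose and 0 fell, and with the block 16 and 3. COL3A1 rose from 7979 ± 3265 to 21243 ± 2889 (2.83-fold, adjusted p = 0.04), a call that ended with quantile normalization. COL1A1 was 17274 ± 2943 and 20665 ± 3161 (adjusted p = 0.4), COL1A2 15988 ± 2411 and 27252 ± 4654 (adjusted p = 0.056), and fibronectin FN1 16746 ± 4000 and 22875 ± 5034 (adjusted p = 0.19). The last 2 passed the threshold with the run block (0.023 and 0.0013), and LAMA2, 1.89-fold up at an adjusted p of 0.03, missed it there (0.063). The list of matrix proteases held 4 genes that rose and 1 that fell of 31, as over the list alone (adjusted p = 0.15), the risers including ADAMTS5, the plasminogen activator PLAT 2.43-fold and cathepsin K, CTSK, 2.31-fold. The collagenase MMP1 stood at 3992 ± 1451 and 2213 ± 572 (adjusted p = 0.077, and 0.0085 with the block). Of integrin and adhesion genes 4 of 32 rose and 5 fell, 4 and 6 over the list alone (adjusted p = 0.17), ITGA2 rising 2.14-fold and N-cadherin, CDH2, falling 2.66-fold. In the chondroitin sulfate and hyaluronan list 2 of 33 rose and 2 fell, as over the list alone (adjusted p = 0.36), with CSGALNACT1 6.25-fold up and XYLT1 4.09-fold down. Without 48 h replicate 1 the rising and falling genes were 3 and 0 for proteases, 2 and 2 for integrins and adhesion, and 1 and 2 for chondroitin sulfate and hyaluronan. With the run block they were 17 and 4, 6 and 9, and 4 and 7.

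Camera placed lists of chaperones and biosynthesis lower at 48 h, with part of each list called. Of 20 heat shock genes 8 fell and none rose, 14 over the list alone (median -0.76, -0.92 with the block, adjusted p = 6.1e-08, and adjusted p = 0.016 with an estimated correlation), with the co-chaperone STIP1 2.94-fold and HSPH1 2.6-fold down. Of 33 genes of the unfolded protein and amino acid response 9 fell, 11 over the list alone (median -0.45 without and with the block, adjusted p = 3.1e-07, and adjusted p = 0.21 with an estimated correlation), among them asparagine synthetase ASNS 4.06-fold, the chaperone HYOU1 4.12-fold and the amino acid transporter SLC7A5 2.56-fold. Of 26 contractile genes 7 fell, 8 over the list alone (median -0.49, -0.44 with the block, adjusted p = 9.2e-07, and adjusted p = 0.096 with an estimated correlation): TAGLN 5.67-fold, smooth muscle actin ACTA2 2.86-fold and TPM1 2.57-fold. Of 28 nucleolar genes 6 fell, 9 over the list alone, with NOP16 2.92-fold down (median -0.46, -0.45 with the block, adjusted p = 3.6e-06, and adjusted p = 0.14 with an estimated correlation). Sterol synthesis held 3 falling genes of 23, 3 over the list alone, such as SQLE 1.97-fold (median -0.46, -0.47 with the block, adjusted p = 0.0055, and adjusted p = 0.46 with an estimated correlation). Of the immediate early genes 18 of 30 fell, 21 over the list alone (median -1.58, -1.43 with the block, adjusted p = 3.8e-14, and adjusted p = 0.14 with an estimated correlation). Fewer fell without 48 h replicate 1: 3 heat shock genes, 5 of the unfolded protein and amino acid response, 1 contractile, 1 nucleolar, 0 sterol synthesis and 9 immediate early genes. Under the block the falling genes were 13, 16, 11, 10, 8 and 19 in the same order, and 1 heat shock, 1 nucleolar, 4 sterol synthesis and 2 immediate early genes rose.

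The cell cycle lists had lower medians at 48 h, by an amount that differed with the run block. For G2/M genes the median was -1.72 with 1 of 51 called, 1 over the list alone (adjusted p = 3.4e-08, and adjusted p = 0.68 with an estimated correlation), and -2.65 with 48 called under the block. The 1 called gene, the spindle checkpoint protein BUB3, fell 2.69-fold. For S phase genes the median was -0.78 with 2 of 43 called, 1 over the list alone (adjusted p = 1.8e-06, and adjusted p = 0.66 with an estimated correlation), and -0.92 with 24 called under the block, the DNA clamp PCNA falling 3.21-fold. MKI67 was 1030 ± 598 at 1 h and 344 ± 33.6 at 48 h (adjusted p = 0.24, and 3.6e-05 with the block). Of the hypoxia and glycolysis genes 17 of 41 rose and 1 fell, 20 and 3 over the list alone (median 0.5, 0.44 with the block, adjusted p = 0.0011, and adjusted p = 0.66 with an estimated correlation), a camera call lost with the run block (0.19). Leaving out 48 h replicate 1, 6 of these rose and 0 fell, and 0 G2/M and 0 S phase genes were called, while with the block 15 hypoxia and glycolysis genes rose and 4 fell.

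Of 26 cytokine and NF-kB genes 7 rose at 48 h, 8 over the list alone and 12 with the block (median 0.59, 1.04 with the block, adjusted p = 0.02, and adjusted p = 0.75 with an estimated correlation), but without 48 h replicate 1, 0 were called and camera gave an adjusted p of 0.92 in the downward direction. The chemokine CXCL1 was 3886 ± 3327 at 48 h against 578 ± 480 (6.51-fold, adjusted p = 0.0093), and the prostaglandin synthase PTGS2 was 6412 ± 4688 against 1103 ± 775 (6.42-fold, adjusted p = 0.023). The respiratory chain list lay lower, with 3 of 45 genes falling, 3 over the list alone and 16 with the block, and CYCS 3.4-fold down (median -0.18, -0.3 with the block, adjusted p = 0.0052, and adjusted p = 0.75 with an estimated correlation), whereas without 48 h replicate 1 it lay upward (0.17) and 1 gene fell. IL6 at 5894 ± 5610, CXCL8 at 12470 ± 6810 and VEGFA at 4244 ± 557 did not differ from 1 h past the threshold (adjusted p = 0.75, 0.28 and 0.24).

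At 48 h 2026 probe sets were called, 1065 higher and 961 lower, and 7589 with the run block (5137 higher and 2452 lower), 1914 of the 2026 among them in the same direction. Array weights, which were 0.282 for both 48 h arrays, gave 557 (241 higher and 316 lower), fewer than at 4, 8, 12 and 24 h. Deposited values without scaling gave 643 higher and 1209 lower, and the scaling moved the median change of all probe sets from 0.032 to 0.19. No run holds arrays of both times, so no within-run value exists. Without 48 h replicate 1 the count was 651, without 48 h replicate 2 it was 4992 (3415 higher and 1577 lower), and without 1 h replicates 2 and 3 it was 1097 and 1328. Of 67 calls 38 held with any array left out, among them ADAMTS5, POSTN, LAMA4, COL18A1, FGF7, NRG1, PDGFRA, PLAT, CTSK, DDAH1, PSAT1, HAS2, XYLT1, CSGALNACT1, STIP1, HSPH1, ASNS, HYOU1, SLC7A5, TPM1, CDH2, NOP16 and CYCS. Leaving out 48 h replicate 1 ended 26, including those of COL3A1, TAGLN, ACTA2, SQLE, PCNA, BUB3, ITGA2, CXCL1 and PTGS2, 1 h replicates 2, 3 and 1 ended 12, 11 and 7, and each of 12 further arrays ended 2 to 5. Array weights ended 23 calls at 48 h, among them those of LAMA4, LAMA2, COL18A1, COL3A1, PLAT, VEGFC, ACTA2, ITGA2, CXCL1 and PTGS2.

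Over the whole course the slope on log2 of time was called for genes of several kinds, which does not mean that they moved evenly. CSGALNACT1 and TXNIP rose by 0.54 and 0.52 per doubling of the hours (SE 0.07 each, limma adjusted p = 6.2e-05 and 6.6e-05), RGS17 by 0.49 (SE 0.04) and BNIP3L by 0.4 (SE 0.04, adjusted p = 2.3e-06). The slope of FOSB was -0.9 (SE 0.12), of HES1 -0.55 (SE 0.06), of DDAH1 -0.53 (SE 0.05) and of TPM1 -0.25 (SE 0.02, adjusted p = 1.7e-06). Of contractile genes 10 of 26 fell, 17 over the list alone and 16 with the block (camera adjusted p = 6.7e-09, and adjusted p = 0.034 with an estimated correlation). Their median slope was -0.1, and -0.11 with the block. Of immediate early genes 22 of 30 fell, 24 over the list alone (median -0.3 without and with the block, adjusted p = 4e-18, and adjusted p = 0.14 with an estimated correlation). So did 8 of 20 heat shock genes, 13 over the list alone with 1 rising (-0.1, -0.11 with the block, 2.3e-06, and adjusted p = 0.13 with an estimated correlation). Falling too were 8 of 28 nucleolar genes, 9 over the list alone (-0.06 without and with the block, 2.5e-07, and adjusted p = 0.16 with an estimated correlation). The count was 8 of 33 for the unfolded protein and amino acid response, 10 over the list alone (-0.07 without and with the block, 9.8e-06, and adjusted p = 0.25 with an estimated correlation). It was 8 of 23 for sterol synthesis, 10 over the list alone (-0.07, -0.1 with the block, 0.00034, and adjusted p = 0.29 with an estimated correlation). Of S phase genes 6 of 43 fell, 8 over the list alone and 20 with the block (-0.14, -0.12 with the block, 2.4e-08, and adjusted p = 0.54 with an estimated correlation). Of G2/M genes it was 0 of 51, also 0 over the list alone, and 24 with the block (-0.18, -0.24 with the block, 1.9e-06, and adjusted p = 0.71 with an estimated correlation). Of TGF-beta targets 7 of 27 fell and 1 rose, as over the list alone (-0.02 without and with the block, 0.0068, and adjusted p = 0.29 with an estimated correlation). Rising were 21 of 41 hypoxia and glycolysis genes, with 1 falling, 25 and 3 over the list alone (0.14, 0.12 with the block, 2.9e-07, and adjusted p = 0.33 with an estimated correlation). So were 13 of 41 ribosomal proteins, 14 over the list alone (0.04, 0.05 with the block, 0.00017, and adjusted p = 0.53 with an estimated correlation). Of matrix genes 10 of 39 rose and 1 fell, 13 and 4 over the list alone, and 10 and 3 with the block (0.09, 0.04 with the block, 0.034, and adjusted p = 0.66 with an estimated correlation). This last call ended with the block (0.47) and with the median over a gene's probe sets (0.06). Without 48 h replicate 1 the slope was called as falling for 5 nucleolar, 4 sterol synthesis and 3 S phase genes, and as rising for 4 matrix genes.

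The slope was called for 2576 probe sets, 1437 rising and 1139 falling, for 5273 with the run block (3518 rising and 1755 falling), 2146 of them shared in direction, and for 2656 within run 4. Deposited values without scaling gave 961 rising and 1343 falling, and without both 48 h arrays 1372 were called.

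The camera calls that held with an estimated correlation were 6 of 75: immediate early genes at 4, 8, 12 and 24 h, heat shock genes at 48 h and contractile genes over the slope. With the run block and an estimated correlation none of the 196 tests was called. With the run block 171 of the 172 called gene results named here or kept beside them were called as well, LAMA2 at 48 h being the exception. These results were picked by tests on the same arrays, and the block called more probe sets at each time from 4 h. Their retention is therefore no separate evidence against a run effect.

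**Figure D5:**
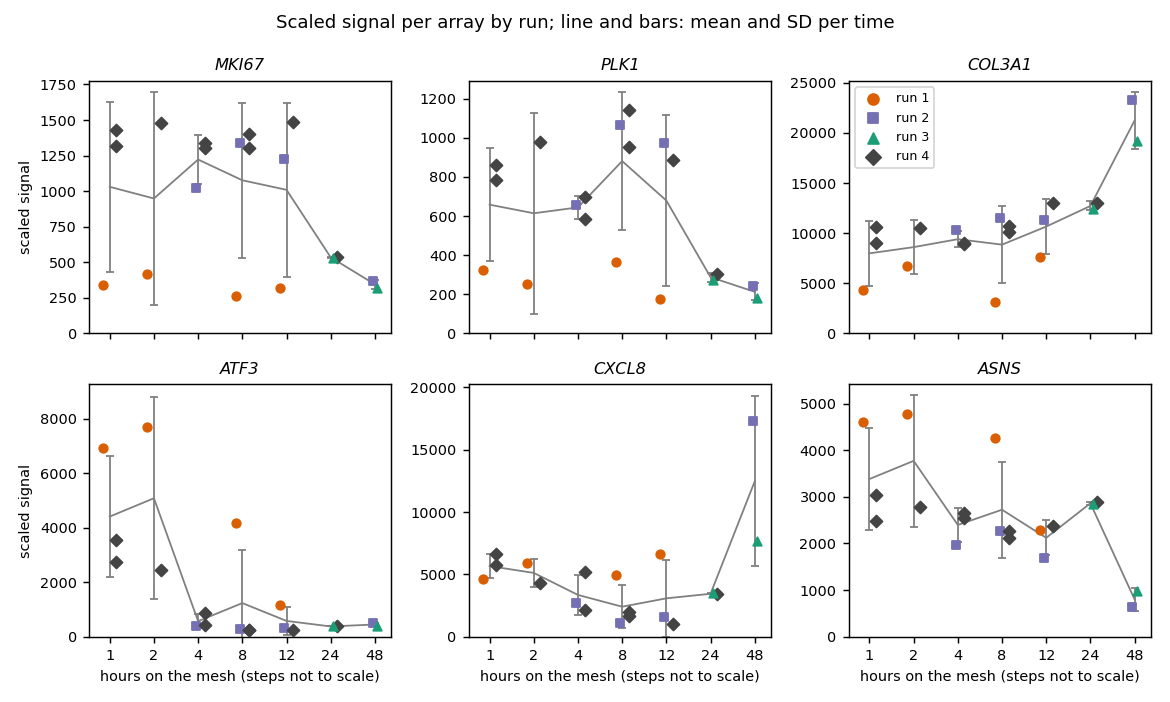
Scaled signal per array (vertical axis) against hours on the mesh for MKI67, PLK1, COL3A1, ATF3, CXCL8 and ASNS, with marker by run and a line with bars for mean and SD per time. At 8 h the run 1 array lies at 259 for MKI67, against 1305 to 1400 on the others.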

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

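The test of the 48 h count with the run as a block was chosen only after the result was seen, as were the block values set beside the other tests of run composition. No cells before seeding or on another surface were used here, so time on the mesh, as the biological explanation, stays untested against handling.

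Single arrays far from the others were looked for at 8 h, the only time with 4 arrays, by the gap to the nearest other array relative to the range of the group. Of 122 genes tested 16 had such an array, where chance gives about 1 in 20 for 4 arrays that could be exchanged freely. The 8 h arrays came from runs 1, 2 and 4, and the genes were those kept for the text. The excess is therefore a description and no test of chance. In 14 of the 16 genes it was 8 h replicate 1, the array of run 1. It was higher for ATF3 at 4171 (others 237 to 271), IL6 at 1608 (449 to 551), CXCL3 at 296 (54 to 77), EGR1 at 1203 (469 to 536), RGS4 at 1925 (430 to 630), G0S2 at 1064 (192 to 315), GADD45B at 1005 (593 to 630), CDKN1A at 6971 (3074 to 3722), ASNS at 4260 (2111 to 2261) and PSAT1 at 4157 (1456 to 1871). It was lower for MKI67 at 259 (1305 to 1400), COL3A1 at 3107 (10115 to 11508), THY1 at 1301 (3354 to 3646) and IRF7 at 121 (147 to 151). ERO1A was 732 in 8 h replicate 3 (447 to 484), and HES1 was 203 in 8 h replicate 2 (244 to 248).

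Hypoxia and glycolysis genes were higher at 12 h than at 1 h, by a median log2 of 0.46. A shift shared by probe sets of like signal is argued against, since the median lay above 100% of 10000 random lists matched on signal, the highest of which reached 0.2. 3′ bias of the arrays is argued against only as far as the GAPDH and ACTB ratios measure it, with a median of 0.69 when both 3′ to 5′ ratios were covariates. Bias of single transcripts that these ratios miss was not tested. Run composition of the times stays open, because the runs disagreed. The change was 0.07 within run 1, under the bound of 0.23, but 0.7 within run 4 and 0.48 with the run as a block. The run 1 value rests on 1 array per time, and that of run 4 on 2 arrays at 1 h and 1 at 12 h.

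Immediate early genes were lower at 8 h than at 1 h, by a median log2 of -1.34. For the run composition of the times, the value within run 1 was -0.66, just short of the bound of -0.67, while run 4 gave -1.77 and the block -1.28, so part of the size stays open. Handling of the cells at seeding cannot be told apart from time on the mesh, since 0 arrays hold cells before seeding or on another surface.

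More probe sets were called at 48 h than at earlier times, but array weights turned this order, with 557 at 48 h against 2513, 2776, 2949 and 2499 at 4, 8, 12 and 24 h. At a time with 2 arrays both get the same weight by construction, 0.282 at 48 h. Replicate 2 was thus weighted down along with replicate 1, so the turned order cannot decide between them. Run composition of the times cannot be told apart from time on the mesh: with the run as a block 7589 were called at 48 h and 2091 at 24 h, but no run holds both 1 h and 48 h arrays. The 48 h replicate 1 array, which stands apart, stays open too: without it 651 were called at 48 h and 430 at 24 h, which met the bound against it, but with the run as a block as well the order turned, at 1084 and 1368. That bound was wrong in passing over the runs, which the 48 h arrays share with no 1 h array.

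Other groupings of the arrays were counted too. For the F test 2 of 100 assignments of the arrays to the times, the real one with 896 probe sets included, gave as many. The other gave 2016, and how it grouped the arrays was not examined, so its cause was not tested. For 8 h against 1 h, 1 of 35 splits gave as many as the real 135. The highest other split, with 85, put the run 1 array of 8 h with the 1 h arrays, and the run block gave 995 for the real one. Both counts exclude chance only for arrays that could be exchanged freely, which the 4 runs do not allow, so chance within the runs stays open. For 4 h and 12 h against 1 h, 1 of 10 splits each gave as many, and the splits are too few for a share under 0.05, with real values of 32 and 296 and 0 as the highest other.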

How the results depend on the processing

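The tests without both 48 h arrays, with the run block and without 48 h replicate 1, for lists without that array, and with the run block and an estimated correlation were chosen after seeing the data. Of 204 gene results, pseudocounts of 64 and 8 left 204 and 201 on their side of the threshold, quantile normalization 187, the run block 185 and array weights 172. None of the 172 results called in the main setting changed direction. A change of direction was not counted for the results that were not called. Leaving out 1 array left 3438 as they were, made 416 weaker and 22 stronger, and 81 of 172 calls held with any array left out. Where it left 1 array at a time, that array was assumed to vary like the others. Of 75 list calls 70 held with the median over a gene's probe sets, 60 with the run block, 71 without 48 h replicate 1 and 6 with an estimated correlation. Counts stayed within 1.5 times under the pseudocounts, the filters, no scaling and no trend in the prior variance, and 2 h against 1 h stayed at 0 throughout. Signal over background limits genes of low signal, since the pseudocount shrinks their changes.

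Counts are given for the F test and 4, 8, 12, 24 and 48 h against 1 h in turn, and the cause was not tested unless stated. Array weights gave 4453, 2513, 2776, 2949, 2499 and 557, which turned the order of 48 h and the earlier times; they ran from 0.282 for both 48 h arrays to 8.39 for 4 h replicate 2. The run block gave 4345, 104, 995, 1403, 2091 and 7589, and 5273 for the slope. The run as a random block gave 3355, 176, 969, 1431, 1542 and 6262, and 4043 for the slope. The 6 tags as a block gave 3852, 69, 874, 1292, 1019 and 6571, and 4093 for the slope. Run 4 alone gave 82 at 4 h, 731 at 8 h, 810 at 12 h and 2056 at 24 h. In run 4 the counts at 12 h and at 24 h each rest on 1 array of that time. The spread there was taken from other times of the run, so these counts cannot serve as a check. Among the 6 tags, 24 h replicate 2 and 48 h replicate 2 are each the only array of their tag. The tag block therefore takes both arrays out. Its counts at 24 h and 48 h rest on replicate 1 of each time, which at 48 h is the array that stands apart. The tag block counts at these times cannot serve as a check either, and its F test and slope do not draw on the arrays taken out. Only the arrays of the compared times gave 5, 10, 7, 26 and 162, with fewer arrays to estimate the spread. Quantile normalization gave 21 at 4 h. A 2-fold change besides the threshold left 190 at 12 h and 1158 at 48 h, by construction. Without both 48 h arrays the F test gave 378 and the slope 1372. The run block without 48 h replicate 1 gave 1446 for the F test and 1084 at 48 h.

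Leaving out 1 array gave ranges of 606 to 1415 for the F test, 0 to 0 at 2 h, 4 to 69 at 4 h, 48 to 203 at 8 h, 86 to 386 at 12 h, 27 to 430 at 24 h, 651 to 4992 at 48 h and 1869 to 2977 for the slope. List directions reversed for G2/M at 4 h with the run block (camera adjusted p = 1.7e-15, and adjusted p = 0.3 with an estimated correlation), for oxidative phosphorylation at 24 h with it (0.22, and adjusted p = 0.87 with an estimated correlation), and without 48 h replicate 1 for cytokines (0.92) and oxidative phosphorylation (0.17) at 48 h. Run 1 holds a 1 h array and no 4 h array. Its G2/M genes lay below those of run 4 at 1 h, by a median of -2.52. The G2/M median at 4 h without the block thus includes this difference between runs. For the other reversals the cause was not tested.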

Other observations

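The comparison of run 1 with run 4 was chosen after seeing the data and is a description, with no test.

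Of 30 interferon response genes 8 rose with log2 of time and none fell, 8 over the list alone (median slope 0.05, 0.07 with the block, camera adjusted p = 0.014, and adjusted p = 0.44 with an estimated correlation). IFITM1, an interferon-induced membrane protein, went from 871 ± 141 at 1 h to 1880 ± 93.3 at 24 h and 2178 ± 1505 at 48 h, a slope of 0.23 (SE 0.05, limma adjusted p = 0.0029). Of 23 p53 targets 2 rose and 1 fell at 24 h, 5 and 1 over the list alone and 8 and 1 with the block (median 0.23, 0.47 with the block, 0.41 within run 4, adjusted p = 0.042, and adjusted p = 0.55 with an estimated correlation), a camera call that ended without 48 h replicate 1 (0.054) and with the median over a gene's probe sets (0.11). At 48 h camera did not call this list (adjusted p = 0.67), with 4 genes rising and 1 falling, 6 and 3 over the list alone, 10 and 3 with the block, and 2 and 2 without 48 h replicate 1. The kinase PLK2 was 4.32-fold higher and the stress-induced GADD45B 3.35-fold lower than at 1 h. Ribosomal proteins lay above the other genes at 48 h, with 2 of 41 rising, 1 over the list alone (median 0.28, 0.29 with the block, against 0.19 for all probe sets, adjusted p = 0.0034, and adjusted p = 0.66 with an estimated correlation). With the block 22 rose, and without 48 h replicate 1 only 1 did.

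Markers of other cells and control genes were looked at for 48 h. PTPRC, a leukocyte antigen, was 173 ± 31.7 at 1 h and 228 ± 56.5 at 48 h (adjusted p = 0.18), and 0 of 10 leukocyte markers were called by limma, 0 over the list alone (camera adjusted p = 0.34). With the run block 9 of the 10 rose (median 0.58 against 0.33 without it, adjusted p = 0.029, and adjusted p = 0.62 with an estimated correlation). Of 6 endothelial markers 1 fell, 1 over the list alone (adjusted p = 0.6), and with the block 3 rose and 2 fell (0.84). Of 9 epithelial markers 1 fell, KRT18, 1 over the list alone (adjusted p = 0.64), and under the block 7 rose and 1 fell (0.17). Among all 16120 probe sets 5137 were called higher and 2452 lower at 48 h with the block. The scale factor was highest, 1.76, for 48 h replicate 1, and whether this bears on signals as low as that of PTPRC was not tested. The marker counts with the block are therefore not read as a change of cell type. Without 48 h replicate 1 no endothelial marker was called. None of 7 metallothioneins was called (adjusted p = 0.14), with MT1X at 15791 ± 1881 and 13854 ± 268. Of 12 housekeeping controls 2 rose and 3 fell (adjusted p = 0.45), 2 and 5 with the block, and 1 and 1 without 48 h replicate 1.

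Of all lists G2/M differed most between run 1 and run 4. Its 51 genes lay lower in run 1 at each shared time, by medians of -2.52 at 1 h, -2.69 at 2 h, -2.74 at 8 h and -2.92 at 12 h, and S phase genes by -1.29, -1.19, -0.78 and -0.51. The unfolded protein and amino acid response lay higher, by 0.66, 0.41, 0.46 and 0.16. Cytokine genes differed by -0.39 at 1 h and 0.93 at 12 h, and metallothioneins by 0.18 and 0.8. Immediate early genes differed by -0.05 at 1 h and 1 at 8 h, hypoxia and glycolysis genes by 0.2 at 1 h and -0.58 at 12 h, and housekeeping controls by 0 at 1 h and -0.19 at 12 h.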
